A study of Homo sapiens with 10 samples.

How the data were processed

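Capture Hi-C measures which stretches of DNA lie close to a chosen locus inside the nucleus: cross-linked chromatin is digested and ligated, and ligation products that carry the chosen locus are pulled out with baits before sequencing. Here the locus was CSF1R, the gene of the receptor for colony-stimulating factor 1, which monocytes and macrophages depend on. Per the labels' protocols, the authors made Hi-C libraries with the Arima kit and captured them with biotinylated RNA baits over a target of 35413 bp. The target was a CSF1R transcript with 1000 bp on either side. Per the labels' protocols, 1474 baits of 70 nt were designed with 3-fold tiling, and 123 baits were filtered out.

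The study has 10 libraries. The 6 groups were taken from the labels: primary monocytes (3 libraries), primary macrophages (3 libraries), and 4 conditions of HL-60 (1 library each). HL-60 is a human promyelocytic leukaemia cell line. Its wildtype form and a CRISPR/Cas9 mutant of the EGR1 binding site in FIRE, an enhancer inside the CSF1R gene, were each left untreated or treated with the phorbol ester PMA, which drives the line towards monocytic cells. EGR1 is a zinc-finger transcription factor. The labels do not say whether the replicates of a primary group came from separate donors, so p-values measure only the spread between these libraries, which may be technical.

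Per the submitters' processing notes, HiC-Pro and genome build hg19 were used; the version is not given in the sources used here, nor is the caller that made the lists. The deposited data are a list per library without headers. Each listed item is a pair of bins of about 5 kb: a bait bin in the CSF1R window and an other-end bin elsewhere. For each pair the authors deposited a whole number and a decimal value, and the meaning of these columns was read from their values, not from a header. The deposited whole number was read as a count of read pairs, not normalized. The deposited decimal value was read as a score from the caller, whose scale and background model are not given in the sources used here. Every list starts at a score of 5 to 5.1, so pairs below 5 are not used here. The score is taken as the authors' own and is used only to rank or filter pairs within a list.

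Across the 10 lists there are 6161 distinct pairs and 4940 distinct other-end bins, with a median bin length of 5120 bp. The bait bins number 8 and span chromosome 5, positions 149430590 to 149472093 (hg19, 1-based). From the target length and flank, the 5′ end of the baited transcript lies between 149465510 and 149470011, in the bait bins at 149461505 to 149466509 and 149466510 to 149472093. These 2 bins are called the promoter-end bins. CSF1R lies on the minus strand, so higher coordinates are upstream of its promoter, on the side of its neighbour PDGFRB. The position of FIRE inside the bait bins was not given in the sources used here, so FIRE has no bin of its own.

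A list holds only pairs past a threshold, so a pair missing from it may have had reads. The sum of listed counts is not a library's depth, and the depth is unknown. For that reason a model of counts between groups was not used, and the branch of the design fixed for thresholded lists was followed. Monocytes and macrophages were compared by per-library values with an exact two-sided permutation test of the mean (smallest possible p 0.1 for 3 against 3, so no test could pass 0.05), adjusted over 9 tests by Benjamini-Hochberg. They were also compared by the number of pairs listed in all 3 libraries of a group and none of the other, set against the 9 other splits of the 6 libraries. HL-60 conditions have 1 library each, so values are given with no test across conditions. Fisher's exact test of chromosome 5 pairs against the rest compares the 2 libraries, not the conditions. Shares from single libraries have exact Clopper-Pearson 95% intervals, which cover counting error only.

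Distances run between bin midpoints. The upstream share is the share of chromosome 5 pairs ending outside the baited window whose other end has a higher coordinate. Overlap of lists is the Jaccard index, shared pairs over all pairs of both lists. A primary set holds the pairs listed in at least 2 of the 3 libraries of a group. Windows of 100 kb were counted within about 2 Mb of the baited window, as shares of a library's pairs in all 41 windows. The script that finds group-exclusive pairs was tested on simulated lists: of 50 planted pairs it recovered 100%, with 13 further pairs arising by chance, and 58% when each planted pair was missed at random in 1 of 5 lists, against 51.2% expected.

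Named pairs followed a rule fixed before the data were examined. For monocytes against macrophages these are the 10 exclusive pairs with the largest mean count. For each HL-60 comparison they are the 5 highest-scoring pairs found only in either library outside the baited window, and for every library its strongest pair there. Pairs on sex chromosomes count in the totals and were passed over in naming. The gene table at hand is on GRCh38, a different build, so it gave only the order of genes around CSF1R, and contacts were not placed on genes. Chromosomes 10 and 20 hold no listed pair in any library and were not analysed here.

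Alternatives fixed before the data were examined were a stricter count limit (at least 2 times a library's lowest listed count), chromosome 5 pairs of at least 20 kb only, no pairs inside the baited window, sharing within 1 bin, lists limited to their 222 strongest pairs, weighting by count, each primary replicate left out, the replicate number as a block, and other definitions of a primary set. A score of at least 10, pairs within 2 Mb, random thinning of the macrophage lists (100 draws) and leaving out 2 monocyte libraries were chosen after seeing the data, as was the rule for far regions of chromosome 5: runs of 5 Mb bins with more primary pairs beyond 2 Mb than an even spread. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.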

Results

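Contacts of the CSF1R locus were listed in 3 libraries of primary monocytes, 3 of primary macrophages and 4 of HL-60 cells, a promyelocytic leukaemia line, with 1 library for each genotype and treatment. The monocyte lists held 222, 279 and 539 pairs and the macrophage lists 504, 1039 and 1105. In HL-60, the wildtype lists held 795 pairs untreated and 1876 with PMA, and the FIRE mutant lists held 412 untreated and 264 with PMA. The read pairs behind the listed pairs summed to between 3031 and 31710 per library, which is not the depth of a library. The median count of a listed pair was 7 to 12 read pairs.

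**Figure D1:**
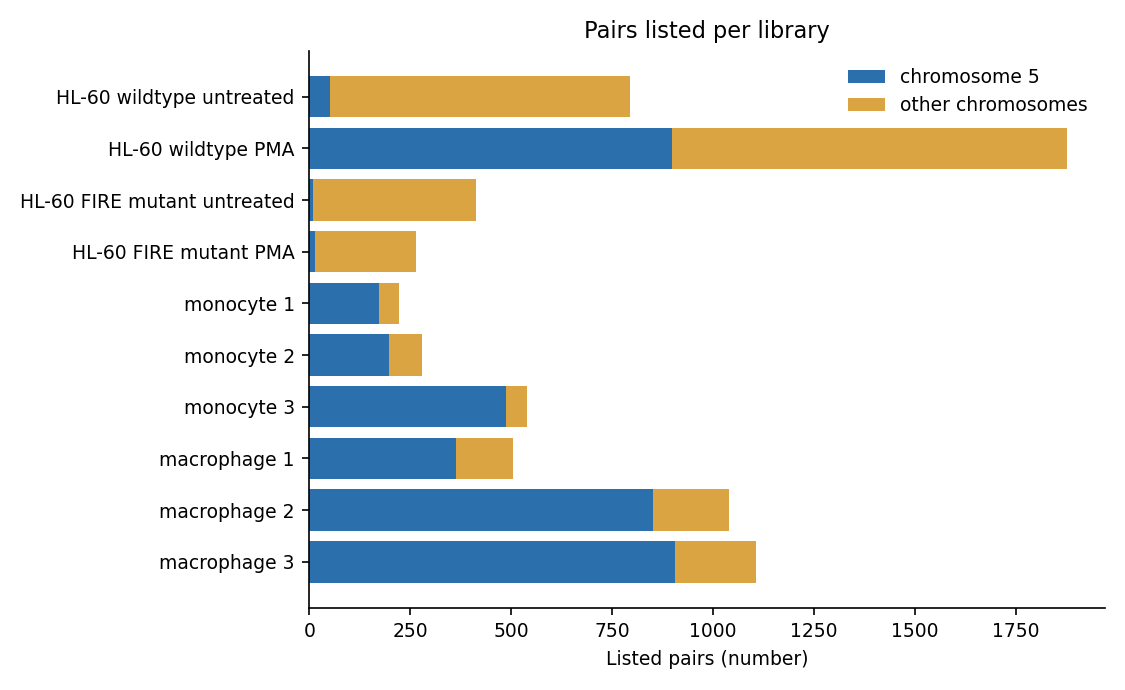
Bars give the number of listed pairs in each of the 10 libraries (horizontal axis), split into pairs whose other end lies on chromosome 5 and on other chromosomes. Chromosome 5 makes up 70.6% to 90.5% of each primary list, 47.8% of the HL-60 wildtype PMA list and at most 6.29% of the other 3 HL-60 lists.

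The primary cells were compared first, to ask how contacts of CSF1R differ between monocytes and macrophages. Macrophage lists were longer, with 883 ± 330 pairs (SD, n = 3) against 347 ± 169 in monocytes. Pairs with other chromosomes numbered 177 ± 30.4 in macrophages and 60.7 ± 18.5 in monocytes, with no overlap between the groups. Chromosome 5 took a similar part of the lists, 78.5% ± 5.82 in macrophages and 79.7% ± 10.1 in monocytes. The exact two-sided permutation test gave p = 0.2 for all pairs, p = 0.1 for pairs with other chromosomes and p = 1 for the chromosome 5 share. No p in this comparison could fall below 0.1, and the Benjamini-Hochberg adjusted values over the 9 tests were 0.257 or higher. The difference of 536 pairs was 325 with a count of at least 2 times the lowest listed and 92.3 with a score of at least 10. The lowest listed counts were 6, 6 and 4 in monocytes and 5, 4 and 4 in macrophages. The stricter count therefore cut the primary lists at unlike counts, here and in the comparisons below.

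Around CSF1R, the contacts of both primary cell types gathered in the same territories. On the upstream side, the side of PDGFRB, the window from 149.7 to 149.8 Mb on chromosome 5 (hg19) held the largest share in both cell types, 20.2% ± 4.84 of macrophage pairs and 12.4% ± 6.79 of monocyte pairs (SD, n = 3). On the downstream side, the window from 149 to 149.1 Mb held 11.7% ± 1.35 of macrophage pairs and 7.48% ± 2.60 of monocyte pairs. Between the downstream territory and the locus, the windows from 149.2 to 149.4 Mb held 2 monocyte pairs and 1 macrophage pair over all 6 libraries. On the upstream side, the windows from 149.5 to 149.6 Mb and from 149.6 to 149.7 Mb held 20 and 9 monocyte pairs and 65 and 79 macrophage pairs; as shares, the window from 149.5 to 149.6 Mb held 6.73% ± 4.53 in monocytes and 6.18% ± 3.50 in macrophages.

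Farther upstream the shares of the cell types parted. The window from 150.1 to 150.2 Mb held 10.2% ± 0.636 of monocyte pairs and 3.38% ± 1.55 of macrophage pairs, and the window from 150.4 to 150.5 Mb held 7.00% ± 1.05 and 2.78% ± 0.602. As numbers of pairs these windows were alike, with 49 in monocytes against 50 in macrophages and 38 against 38. The monocyte lists held 64, 61 and 366 pairs in all 41 windows and the macrophage lists 187, 540 and 559, so similar numbers gave unlike shares. Macrophage shares were higher in the window from 149.6 to 149.7 Mb, with 6.80% ± 2.22 against 2.59% ± 1.06, and on the downstream side from 148.6 to 148.7 Mb, with 2.34% ± 0.796 against 0.182% ± 0.315. In 9 of the 41 windows the shares of the groups did not overlap, 3 higher in macrophages and 6 higher in monocytes, all 6 of them between 150 and 151.2 Mb. Chance gives 10% of windows, and shares of a list are not independent of each other.

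**Figure D2:**
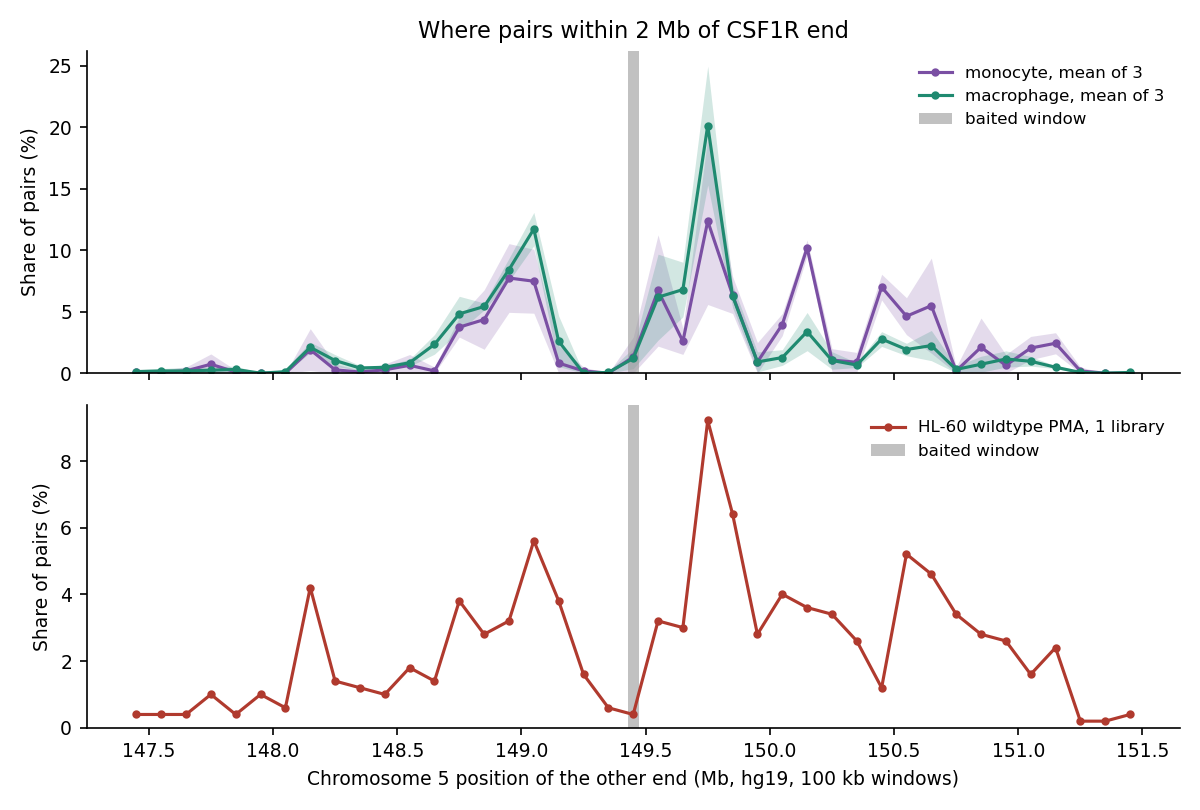
Each point is the share of a library's pairs within about 2 Mb of CSF1R (vertical axis, %) that end in a 100 kb window of chromosome 5 (horizontal axis, Mb, hg19). Lines are means of 3 libraries with bands of 1 SD above, and the single HL-60 wildtype PMA library below; the peak from 149.7 to 149.8 Mb holds 20.2% in macrophages, 12.4% in monocytes and 9.22% in HL-60 wildtype with PMA.

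The side of the locus on which contacts fell was compared directly. Within 2 Mb, 71.1% ± 2.97 of monocyte pairs and 58.6% ± 6.05 of macrophage pairs lay upstream (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Over the whole chromosome the upstream share was 54.3% ± 4.71 in monocytes and 47.1% ± 4.12 in macrophages (exact p = 0.2). When each pair was weighted by its count, this whole-chromosome difference changed sign, with macrophages higher by 4.73 percentage points. Macrophages minus monocytes, the difference of -7.22 points was -4.58 without monocyte 3, -12.1 with the stricter count and -13.0 with 222 pairs per list.

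Contacts of the promoter end of CSF1R made up 16.6% ± 2.47 of macrophage pairs and 13.4% ± 1.34 of monocyte pairs (SD, n = 3; exact two-sided permutation p = 0.1). The difference of 3.25 percentage points was 1.83 without macrophage 3, 1.20 with 222 pairs per list and -3.91 when weighted by count. The weighted value includes pairs of a promoter-end bin inside the baited window. These had 187 of 3031 listed read pairs in monocyte 1, 248 and 360 of 3988 in monocyte 2, and 509 and 634 of 22776 in macrophage 3. The other primary lists held none, so the change of sign rests at least partly on pairs inside the window. The bait bin at 149466510 to 149472093, which reaches the upstream end of the target, gave the fewest pairs of the 8 bait bins in all 10 libraries, between 1.89% and 4.98% of a list. Contact distances had library medians of 7853 ± 6199 kb in monocytes and 1012 ± 315 kb in macrophages (exact p = 0.4). The monocyte libraries disagreed among themselves, with medians of 10376, 12394 and 790 kb, and the difference of -6842 kb, macrophages minus monocytes, was -10373 kb without monocyte 3. It was 1492 kb when each list kept only its 222 strongest pairs, -100.5 kb with the stricter count, -169.8 kb weighted by count, -138 kb within 2 Mb and -624 kb with a score of at least 10.

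A set of 40 pairs was listed in all 3 macrophage libraries and in no monocyte library, and 0 pairs showed the opposite. Of the 40, 35 lay upstream and 5 downstream of the locus, at distances of 56.4 to 775 kb, and they ended in 21 distinct bins. Most of them ended in a stretch at 149589627 to 149615454 and in another at 149687733 to 149755043 on the PDGFRB side, and 13 of the 40 pairs were also listed in HL-60 wildtype with PMA. The highest number in the 9 other splits of the 6 libraries was 34, for monocyte 3 with macrophage 2 and 3, the 3 longest primary lists. The number was 0 with the 222 strongest pairs per list or a score of at least 10, a median of 2 with macrophage lists thinned at random to the monocyte lengths, and 85 when a neighbouring bin counted as shared. With recurrence asked of 2 macrophage libraries, it was 128 without macrophage 1 and 62 without macrophage 3.

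Of the 10 macrophage-only pairs with the largest mean count, 2 joined the bin at 149502491 to 149507500 to the body of CSF1R. Its pair with the bait bin at 149445895 to 149451260 had 348 ± 105 read pairs (SD, n = 3), and its pair with the bait bin at 149430590 to 149435598 had 240.3 ± 68.6. This bin was listed with other bait bins in 2 monocyte libraries. The other 8 ended between 149589627 and 149615454, where only the pairs, and not all of the bins, were absent from the monocyte lists: with other bait bins, 149594797 to 149599904 and 149599905 to 149605021 were each listed in 3 monocyte libraries and 149589627 to 149594796 in 2. The bait bin at 149445895 to 149451260 had 107 ± 21.8 read pairs with the bin at 149594797 to 149599904, 91.3 ± 2.08 with 149599905 to 149605021 and 86.7 ± 6.81 with 149589627 to 149594796. The bait bin at 149435599 to 149440882 had 100 ± 23.5 read pairs with 149589627 to 149594796, 98.7 ± 22.9 with 149599905 to 149605021 and 81.7 ± 22.8 with 149605022 to 149610361. The bait bin at 149440883 to 149445894 had 88.3 ± 15.3 read pairs with 149589627 to 149594796 and 68 ± 13.2 with 149610362 to 149615454. Their mean scores lay between 5.35 and 6.92, close to the limit of the lists.

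Taking other-end bins regardless of the bait bin, 9 bins were contacted in all 6 primary libraries, 19 in all 3 macrophage and no monocyte library, and 1 in all 3 monocyte and no macrophage library. Macrophage lists were longer, which favours macrophage-only bins, and these numbers were not set against other splits or thinned lists. The monocyte bin was 150077795 to 150082867, with 6 pairs. Among the macrophage bins, 149724332 to 149729346 had 17 pairs over the 3 libraries, 149709060 to 149714214 had 14 and 149610362 to 149615454 had 13. The bins at 149813004 to 149818019 and 149497319 to 149502490 were each contacted in 9 of the 10 libraries, and the second of these in all 4 HL-60 libraries. These 5 were chosen after their values were seen.

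Lists of the same cell type shared few pairs. The Jaccard index averaged 8.43% ± 2.30 among macrophage libraries (SD over 3 library pairs), 2.60% ± 1.08 among monocyte libraries and 3.92% ± 2.53 between the cell types. Within-type overlap exceeded between-type overlap by 1.59 percentage points (exact two-sided permutation p = 0.2 over 10 splits). In all 3 macrophage lists 77 pairs recurred, in all 3 monocyte lists 3, and in all 6 lists 0. The difference was -0.0674 without macrophage 2, -0.0462 without macrophage 3, 0.520 without macrophage 1, 2.52 without monocyte 1 and 4.33 without monocyte 3. It was 0.0505 with 222 pairs per list, 0.240 with a score of at least 10, 3.35 with sharing within 1 bin and 3.54 with the stricter count.

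PMA was given to HL-60 to drive monocytic differentiation, and in wildtype cells the list with PMA held more contacts on chromosome 5. With PMA, 897 of 1876 pairs (47.8%, interval 45.5% to 50.1%) lay on chromosome 5, against 50 of 795 (6.29%, 4.70% to 8.21%) untreated. Within 2 Mb of the locus there were 496 pairs with PMA and 8 without. Of the PMA pairs near the locus, 9.22% lay in the window from 149.7 to 149.8 Mb and 5.61% in the window from 149 to 149.1 Mb. The PMA list held 8 pairs from 149.2 to 149.3 Mb, 3 from 149.3 to 149.4 Mb and 3.41% of near pairs from 150.7 to 150.8 Mb, against 0.182% in monocytes and 0.302% in macrophages. From 150.4 to 150.5 Mb it held 1.20%, against 7.00% and 2.78%. The libraries shared 11 pairs, 1865 were listed only with PMA (888 on chromosome 5) and 784 only without (41 on chromosome 5). Fisher's exact test, two-sided, of chromosome 5 pairs against the rest gave p = 5.29e-111, which compares those libraries, not the conditions. The difference of 41.5 percentage points in chromosome 5 share was 16.04 with a count of at least 2 times the lowest listed and 20.3 with 222 pairs per list, where 221 pairs were found only in either library. The stricter count left 1085 pairs only with PMA and 52 only without.

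The counts behind these lists differed. Between 200 and 500 kb, in the 7 lower bait bins, the 5 untreated pairs had at least 48 read pairs each, and the 142 PMA pairs had a median of 30.5 and a minimum of 14. Of the PMA pairs, 21 reached 48. With the bait bin at the upstream end included, the lowest listed counts at 300 to 500 kb were 16 untreated and 7 with PMA. The 4 pairs listed in both libraries at that distance had PMA counts of 0.333 to 0.463 times the untreated counts.

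**Figure D3:**
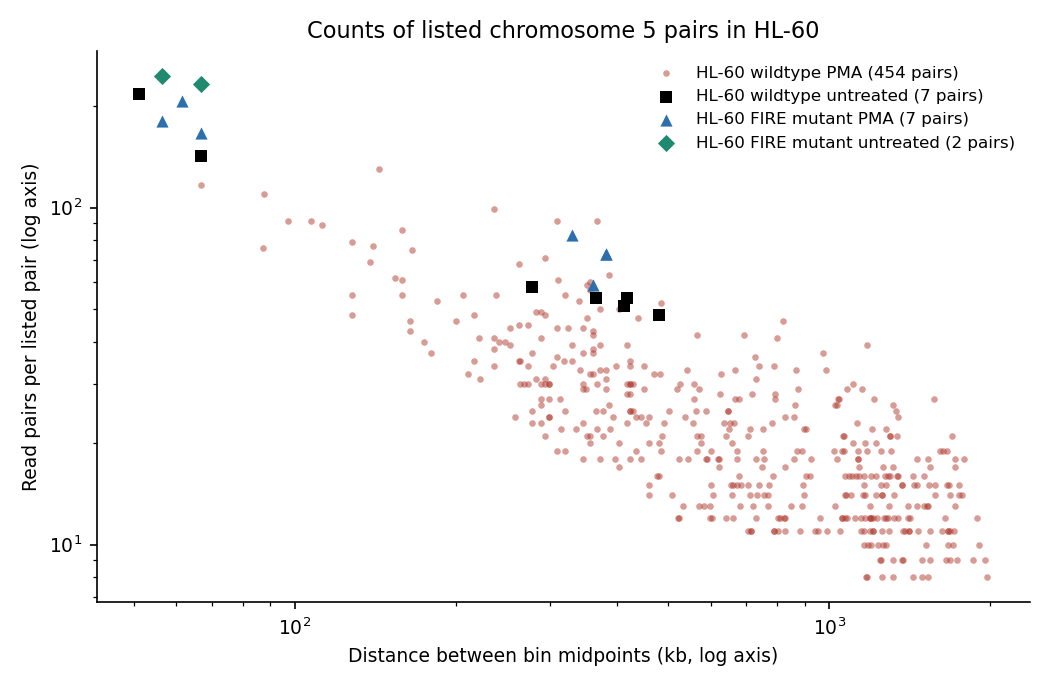
Points are chromosome 5 pairs of the 4 HL-60 libraries between 50 kb and 2 Mb from the bait bin, leaving out the bait bin at the upstream end, with distance in kb on the horizontal axis and read pairs on the vertical axis, both log axes. The 454 wildtype PMA pairs reach lower counts at a given distance than the 7 wildtype untreated, 2 mutant untreated and 7 mutant PMA pairs.

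By score, the strongest pair found only in the wildtype PMA list joined the bait bin at 149456288 to 149461504 with 36748650 to 36753825 on chromosome 5, 112708 kb away, with 44 read pairs and a score of 124. The next joined 149435599 to 149440882 with 135459419 to 135464464, with 39 read pairs and a score of 104. The remaining 3 of the top 5 ended on chromosome 7 at 128448329 to 128453382 and at 44913615 to 44918664, with 36 read pairs each, and on chromosome 2 at 61518646 to 61524094, with 34. Of the top 5 found only untreated, 2 ended on chromosome 6 at 134842315 to 134847439 with 26 read pairs and at 153948938 to 153953989 with 22. The other 3 ended on chromosome 7, at 119882517 to 119887584 with 23, at 22618430 to 22623440 with 20 and at 106763285 to 106768337 with 19.

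In FIRE mutant cells, few contacts near CSF1R were listed with or without PMA. The mutant lists held 8 chromosome 5 pairs of 412 untreated (1.94%, interval 0.842% to 3.79%) and 14 of 264 with PMA (5.30%, 2.93% to 8.74%). Outside the baited window and within 2 Mb these were 3 and 8 pairs, all upstream. Untreated, they ended at 149497319 to 149502490, and with PMA some reached the territory near 149.8 Mb, such as 149813004 to 149818019 with 73 read pairs and 149786839 to 149791872 with 83. The libraries shared 5 pairs, 259 were listed only with PMA (9 on chromosome 5) and 407 only without (3 on chromosome 5). Fisher's exact test, two-sided, gave p = 0.0243, which compares those libraries, not the conditions. The difference of 3.36 percentage points in chromosome 5 share was 17.3 with the stricter count. It was 0.450 with 222 pairs per list and -0.488 with a score of at least 10. The 17.3 points rest on lists of 15 pairs untreated and 17 with PMA, of which 5 and 4 lay inside the baited window. The 16.04 points in wildtype rest on 61 and 1094 pairs. The stricter count left 12 pairs only with PMA and 10 only without.

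The strongest pair found only in the mutant PMA list joined 149456288 to 149461504 with chromosome 13 at 80116175 to 80121500, with 18 read pairs and a score of 51.4. The other 4 of its top 5 had 14 read pairs each and ended on chromosome 1 at 204067203 to 204072233, chromosome 17 at 74437741 to 74442914, chromosome 8 at 136285486 to 136290794 and chromosome 7 at 111513765 to 111518850. The top 5 found only untreated ended on chromosome 16 at 82676422 to 82681588 and chromosome 2 at 218308209 to 218313238, with 15 read pairs each, and on chromosome 6 at 89737907 to 89743141 and at 151519531 to 151524618 and chromosome 1 at 53396209 to 53401251, with 14 each.

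Mutant and wildtype cells were then compared within each treatment, to ask how the locus differs when the EGR1 site is mutated. Untreated, the mutant list had fewer pairs than wildtype, 412 against 795, and the difference in chromosome 5 share, mutant minus wildtype, was -4.35 percentage points. With PMA the gap was wide, 264 against 1876 pairs, and the difference in chromosome 5 share was -42.5 percentage points. The lists shared 7 pairs in either treatment. With PMA, the 3 shared chromosome 5 pairs outside the baited window had higher counts in the mutant: 73 against 33 read pairs at 149813004 to 149818019, 59 against 43 at 149807884 to 149813003 and 83 against 39 at 149786839 to 149791872. Between 300 and 500 kb the lowest listed count was 59 among 4 pairs in mutant PMA and 7 among 103 pairs in wildtype PMA. The 7 came from the bait bin at the upstream end, where mutant PMA listed 0 chromosome 5 pairs outside the baited window. In the other bait bins no wildtype PMA pair at this distance had fewer than 14 read pairs. With such unlike numbers of pairs, the minima alone do not show that a lower count was enough for a listing in wildtype PMA. Fisher's exact test, two-sided, gave p = 0.000552 untreated and p = 1.46e-47 with PMA, again comparing libraries. Against the mutant, the top 5 pairs found only in wildtype untreated also included chromosome 13 at 80116175 to 80121500, joined to the promoter-end bait bin at 149461505 to 149466509 with 24 read pairs. With a count of at least 2 times the lowest listed, the chromosome 5 share was higher in the mutant by 15.6 points untreated and by 16.8 points with PMA. This setting left 15 mutant pairs against 61 in wildtype untreated, and 17 against 1094 with PMA. The full mutant lists held 404 and 250 other-chromosome pairs, so the setting removed most of them. In wildtype PMA more pairs stayed than its 897 chromosome 5 pairs, so other-chromosome pairs stayed too. A count limit only removes pairs, so the higher mutant shares came from the pairs removed. The lowest listed count was 7 in mutant PMA and 6 in wildtype PMA, so those lists were not cut at the same count. With 222 pairs per list the differences were -1.80 and -21.6 points, and untreated it was -2.59 with a score of at least 10.

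Inside the baited window, the promoter-end bait bin at 149466510 to 149472093 was paired with the body of the gene in all 4 HL-60 libraries. Its pair with 149456288 to 149461504 had 1038 read pairs in wildtype untreated, 866 in wildtype PMA, 1338 in mutant untreated and 978 in mutant PMA. Such pairs numbered 5, 3, 5 and 4 in these libraries. Of the 6 primary libraries, 3 listed pairs inside the window, with 1 or 2 pairs each. The promoter-end bins took 13.1% (interval 10.8% to 15.6%) of the wildtype untreated list, 16.6% (14.9% to 18.3%) with PMA, 13.3% (10.2% to 17.0%) of the mutant untreated list and 17.8% (13.4% to 23.0%) with PMA. All 4 intervals overlap. In the same order the shares were 35.5%, 20.1%, 47.4% and 45.5% when weighted by count, with PMA below untreated in both genotypes. These weighted shares include the pairs inside the window. The pair with 149456288 to 149461504 alone made up 1038 of 10516, 866 of 31710, 1338 of 7370 and 978 of 5217 listed read pairs. Weighted shares without pairs inside the window were not computed, so these values do not show how contacts outside it moved with PMA. With the stricter count they were 18.0%, 16.5%, 40% and 29.4% of 61, 1094, 15 and 17 pairs. On chromosome 5 beyond 20 kb they were 20.8%, 19.0%, 50% and 16.7% of 48, 895, 6 and 12 pairs. In both mutant lists the promoter-end bins had 0 chromosome 5 pairs outside the baited window, so 50% and 16.7% come from pairs inside it. With 222 pairs per list the shares were 9.91%, 14.0%, 11.3% and 9.46%, with PMA above untreated in wildtype and below it in the mutant.

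HL-60 lists were set against the primary cells to ask which library shares more contacts with macrophages. The wildtype PMA list held 71 of the 269 pairs of the macrophage set (26.4%, interval 21.2% to 32.1%), the wildtype untreated list 6 (2.23%), the mutant untreated list 2 (0.743%) and the mutant PMA list 6 (2.23%, 0.823% to 4.79%). As a share of each HL-60 list, this was 3.78% (2.97% to 4.75%) for wildtype PMA, 0.755% (0.277% to 1.64%) for wildtype untreated, 0.485% (0.0588% to 1.74%) for mutant untreated and 2.27% (0.839% to 4.88%) for mutant PMA. Of the 50 pairs of the monocyte set, the wildtype PMA list held 10 (20%, 10.03% to 33.7%) and the other 3 lists 0, 1 and 1. Per listed pair, the intervals of the wildtype and mutant PMA lists overlap. With the stricter count, wildtype PMA moved from the highest share to the lowest: 35.3% (6 of 17 pairs, 14.2% to 61.7%) in mutant PMA, 13.3% (2 of 15, 1.66% to 40.5%) in mutant untreated, 9.84% (6 of 61, 3.70% to 20.2%) in wildtype untreated and 6.40% (70 of 1094, 5.02% to 8.02%) in wildtype PMA. Only the interval of mutant PMA lay apart from that of wildtype PMA. The numbers of shared pairs were nearly the same as in the full lists, so these shares moved with the pairs left in each list. Wildtype PMA was also lowest on chromosome 5 beyond 20 kb, at 50% (6 of 12), 33.3% (2 of 6), 12.5% (6 of 48) and 7.93% (71 of 895), and all 4 shares were 0% with 222 pairs per list.

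The strongest single contacts outside the window differed by how strength was measured. By count, the strongest pair ended at 149497319 to 149502490, just upstream of the baited window, in 7 of the 10 libraries, with up to 707 read pairs in macrophage 3. By score, the strongest pair of every primary library lay on chromosome 5 but 6722 to 19938 kb away, with 11 to 16 read pairs. In order away from CSF1R, the protein-coding genes on the upstream side are PDGFRB, CDX1, SLC6A7, CAMK2A, ARSI, TCOF1, CD74, RPS14 and NDST1, and on the downstream side HMGXB3, TIGD6, SLC26A2, PDE6A and PPARGC1B, by their order on GRCh38. PDGFRB encodes a receptor for platelet-derived growth factor, and CD74 the invariant chain of antigen presentation. Contacts were not placed on these genes.

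**Figure D4:**
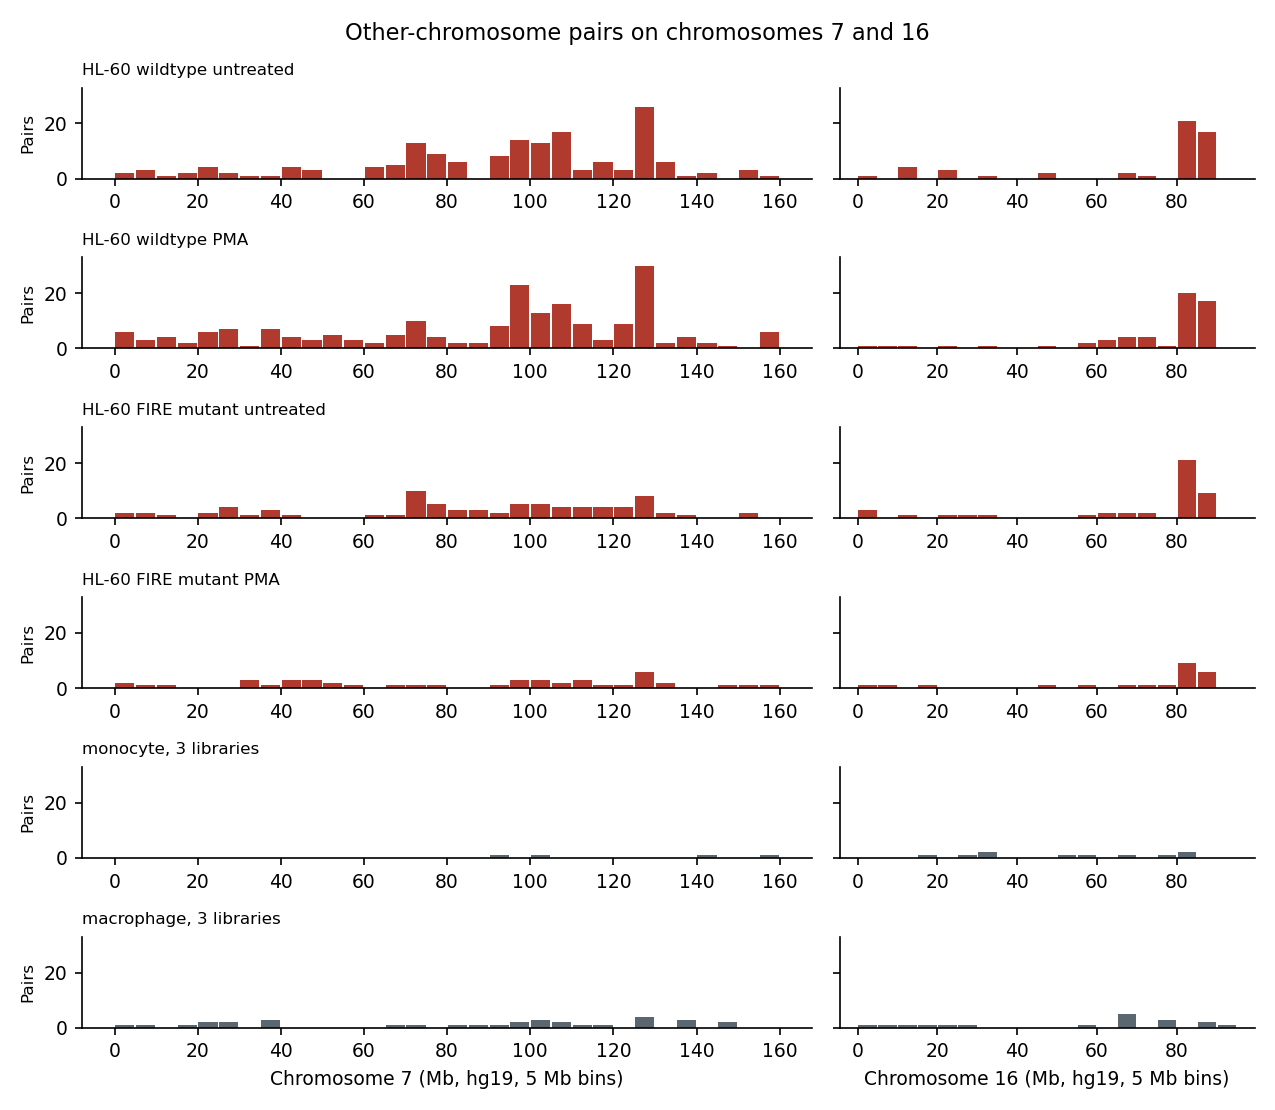
Bars count pairs between CSF1R and 5 Mb bins of chromosomes 7 and 16 (horizontal axes, Mb, hg19), for each HL-60 library and for the 3 monocyte and 3 macrophage libraries added up. In HL-60, pairs gather between 64 and 131 Mb of chromosome 7 and between 81 and 88 Mb of chromosome 16, which together hold 15.8% to 23.2% of autosomal other-chromosome pairs, against 1.22% to 4.35% in the primary libraries.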

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

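All tests in this part were chosen after the results were seen, except the count of other splits for the macrophage-only pairs.

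The number of listed pairs moved in opposite directions with PMA in the HL-60 genotypes: the difference of PMA minus untreated was 1081 in wildtype and -148 in the FIRE mutant, a contrast that was not tested because each condition has 1 library; the mutant list was longer with PMA, as in wildtype, with a count of at least 2 times the lowest listed (17 against 15 pairs) and on chromosome 5 beyond 20 kb (12 against 6).

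In HL-60 wildtype cells, PMA came with 897 listed chromosome 5 pairs against 50 untreated. A primary-cell library under this label is argued against, since 17.4% of its autosomal other-chromosome pairs lay in the chromosome 7 and 16 segments found in the other 3 HL-60 libraries, against at most 4.35% in a primary library; a swap within HL-60 was not tested. In the 7 lower bait bins at 200 to 500 kb, a lower count was enough for a listing in the PMA library. Of its pairs there, 14.8% (9.39% to 21.7%) reached the lowest untreated count of 48. With the remaining bait bin included, the lowest counts at 300 to 500 kb were 16 untreated and 7 with PMA. The lower count may account for most of the added pairs at these distances. Among listed pairs there at or above 48, the PMA library held 21 of 26 (80.8%, 60.6% to 93.4%). That share cannot decide whether the lower count accounts for all of them, because 48 is the untreated list's own lowest count there. Untreated pairs below the score limit are also not listed. Deeper sequencing cannot be told apart from the rest, because the 5 shared pairs inside the window or on other chromosomes had PMA counts of 0.581 to 1.21 times the untreated ones (median 0.843) and the depth is unknown; the 6 shared chromosome 5 pairs outside the window all had lower PMA counts (0.333 to 0.824 times, median 0.444), which goes against it for those pairs. An effect of PMA that needs the EGR1 site stays open and untested, with 1 library per condition. With a count of at least 2 times the lowest listed, the chromosome 5 share was higher with PMA by 17.3 points in the mutant and 16.04 in wildtype. The mutant value rests on lists of 15 and 17 pairs and the wildtype value on 61 and 1094, so their similar size does not decide this.

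Other-chromosome pairs gathered in 2 segments in HL-60; the comparisons of the report count these pairs but do not use where along the other chromosomes they lie. The chromosome 7 segment held 18.1%, 13.9%, 14.8% and 10.1% of autosomal other-chromosome pairs in wildtype untreated, wildtype PMA, mutant untreated and mutant PMA, against at most 4.32% in a primary library, and the chromosome 16 segment held 5.08%, 3.53%, 7.29% and 5.67% in the same order against at most 4.35%, with only the interval of mutant untreated above that value and wildtype PMA below it. Random ligation alone is argued against, since in the wildtype PMA library, which was not used to find the segments, their share exceeded their 2.96% of the length of the autosomes with listed other-chromosome pairs (all but 5, 10 and 20, as 2497 bins of 1 Mb up to the last listed pair of each) by 14.5 percentage points. Candidate explanations are joined chromosome segments in HL-60 and extra copies of the segments: in that library the 4 Mb inside the upper edge of the chromosome 7 segment held 26 pairs and the next 4 Mb held 2, and the same 26 pairs were 19.4% (13.1% to 27.1%) of the segment's pairs, against 5.97% for an even spread, in 4 Mb chosen as the densest in the other 3 HL-60 libraries. Either can give an edge, and uneven chromatin can also crowd pairs, so they cannot be told apart, and no biological explanation from the design was tested.

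The 40 pairs listed in all 3 macrophage and no monocyte library were the most of any split: 1 of the 10 splits gave as many, and the highest other was 34. The 9 separated windows were likewise reached in 1 of the 10 splits, with 7 as the highest other. With 10 splits no share under 0.05 is possible, and in both cases the next split set the 3 longest primary lists against the rest. List length could account for the 40 pairs: of the 214 pairs listed in macrophage 2 and 3, macrophage 1 held 77 and monocyte 3, of similar length, held 72 (47 against 42 in only that library, exact two-sided binomial p = 0.672). Of pairs within 2 Mb, 41.2% in macrophage 1 and 19.7% in monocyte 3 were among these 214, so neither list length nor a difference between the cell types can be set aside.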

How the results depend on the processing

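A score of at least 10, pairs within 2 Mb, random thinning and leaving out monocyte 1 and 2 were chosen after the results were seen. Among primary-cell differences, pairs per library kept its direction in all 11 alternatives, contact distance in 13 of 14, upstream share in 13 of 14, promoter-end share in 11 of 12 and overlap in 10 of 12. Some of these alternatives could not change the value. The replicate block leaves every difference as it is, and the upstream share leaves out pairs inside the baited window in any case. The limit of 20 kb also left contact distance and upstream share unchanged. No p could reach 0.05 in any alternative. Contact distance reversed with 222 pairs per list (1492 kb), and weighting by count reversed the upstream share (4.73 points) and the promoter-end share (-3.91). High-count pairs inside the baited window, listed in monocyte 1 and 2 and macrophage 3, contribute to the promoter-end reversal. Without macrophage 3 the promoter-end difference was 1.83 points. Without a macrophage replicate the overlap difference ranged from -0.0674 to 0.520, and over all left-out replicates up to 4.33. The macrophage-only count ranged from 42 to 128 and the monocyte-only count from 0 to 6 over left-out replicates; sharing within 1 bin gave 85 and 7, thinning gave medians of 2 (0 to 8) and 1 (0 to 3), 222 pairs per list and a score of at least 10 each gave 0, and without monocyte 1 and 2 there were 47 and 359. Shorter lists leave fewer recurrent pairs by construction. The 359 monocyte-only pairs needed a listing in monocyte 3 alone, so that number does not measure recurrence. The cause of the other changes was not tested. The replicate number as a block leaves the differences unchanged by construction, at 536 pairs, -6842 kb, -7.22 and 3.25 points, 40 and 0 exclusive pairs and 1.59 points of overlap. Only a p-value could change, with a smallest blocked exact p of 0.25. Same-numbered libraries correlated at 8.69e-05, -0.00556 and 0.00665, and differently numbered ones at -0.00886 to 0.0102. Because the lists share few pairs, these correlations cannot decide whether equal numbers mark pairing. The labels do not say either, so the numbers are not read as pairing.

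In HL-60, counts are given as shared, only in the first and only in the second library named. With a count of at least 2 times the lowest, wildtype PMA against untreated gave 1085 and 52 exclusive pairs, mutant PMA against untreated 12 and 10, mutant against wildtype 9 and 55 untreated and 12 and 1089 with PMA. On chromosome 5 beyond 20 kb these were 7, 888 and 41, then 3, 9 and 3, then 4, 2 and 44, then 3, 9 and 892. With 222 pairs per list they were 1, 221 and 221 for wildtype, 1 shared and 221 only untreated for the mutant, 0, 222 and 222 between untreated genotypes and 1 shared and 221 only in wildtype with PMA. Sharing within 1 bin raised the shared pairs to 28, 9 and 14 for wildtype, mutant and the genotypes with PMA. The chromosome 5 share difference for wildtype PMA was 16.04, 20.3 and 32.7 points under the stricter count, 222 pairs and a score of at least 10. For mutant PMA it was 17.3 under the stricter count, from lists of 15 and 17 pairs, and reversed to -0.488 with the score. Mutant against wildtype reversed under the stricter count (15.6 untreated, 16.8 with PMA), where the mutant lists held 15 and 17 pairs. The full mutant lists held 404 and 250 other-chromosome pairs, most of which this limit removed, so the reversal came from the pairs removed. The difference between mutant and wildtype was -1.80 untreated and -21.6 with PMA with 222 pairs, and -35.7 with the score and PMA. What moved the other values was not tested. The share of the wildtype PMA list in the macrophage set was 6.40% with the stricter count, 7.93% beyond 20 kb, 0% with 222 pairs or a score of at least 10, 9.65% and 1.33% for pairs listed in any or all 3 macrophage libraries, and 15.4% within 1 bin. In mutant PMA, mutant untreated and wildtype untreated it was 35.3%, 13.3% and 9.84% with the stricter count and 50%, 33.3% and 12.5% beyond 20 kb. Wildtype PMA thus moved from the highest share to the lowest, while mutant PMA stayed above both untreated lists. Under both settings the numbers of shared pairs were nearly those of the full lists, so these shares moved with the pairs left. Among values of single HL-60 libraries under these alternatives, 49 lay inside the 95% counting interval of the reported share or within 1.5 times the reported count or distance, and 88 lay outside; the intervals of short lists are wide. DESeq2, library-total scaling and no low-count filter were not run, since lists hold only pairs past a threshold, and neither were genes contacted and its distance margin, since no gene positions on hg19 were used. Depth, unknown here, limits every comparison of list lengths.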

Other observations

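Far from the gene, the listed chromosome 5 contacts of primary cells were not spread evenly; the regions were delimited after the data were seen. Of pairs more than 2 Mb away, 58.4% ± 21.6 in monocytes and 67.8% ± 5.04 in macrophages (SD, n = 3) ended between 130 and 160 Mb, the stretch around CSF1R. A separate stretch from 165 to 180 Mb, near the far end of the long arm, held 25.9% ± 12.2 and 15.9% ± 3.00. The 5 Mb between these stretches held 4 monocyte and 3 macrophage pairs in all. From the start of the chromosome to 130 Mb the shares were 14.6% ± 8.70 and 15.2% ± 3.13. The exact two-sided permutation p between the cell types was 0.5, 0.4 and 1 for these 3 regions, with 0.1 the smallest possible. In HL-60 wildtype with PMA the stretch from 130 to 160 Mb held 64.1% of far pairs, and untreated 18.9%, where 78.4% ended below 130 Mb.

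Other-chromosome contacts rarely recurred. Over all libraries, 2951 autosomal other-end bins on other chromosomes were listed in 1 library, 27 in 2 libraries and 1 in 3. The recurrent bin lies on chromosome 13 at 80116175 to 80121500 and was contacted in 3 of the 4 HL-60 libraries (wildtype untreated, wildtype PMA and mutant PMA), from 3 bait bins, with 10 to 29 read pairs. It was listed in 0 primary libraries.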
